A study of Mus musculus with 2 samples.

How the data were processed

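Gene expression was measured in C2C12 cells, an established line of mouse skeletal myoblasts, that stably expressed either a short hairpin RNA against Mybbp1a or a control hairpin. Per the labels, each sample was a mixture of stable clones kept subconfluent in growth medium, and total RNA of the knockdown and control cells was labelled with Cy5 and Cy3. Knockdown RNA carried Cy5 and control RNA carried Cy3 on both arrays, so no dye swap was made and a bias of the dyes that normalization leaves in place cannot be separated from an effect of the knockdown. The 2 arrays are described as biological replicates. The labels do not say whether the replicates came from separate infections, separate clone pools or separate cultures of 1 pool. The p-values that limma gave single genes therefore measure only the spread between these samples, which may be technical. The 2 arrays were on different slides, scanned separately, and each slide held 1 array used here, so slide and replicate cannot be told apart.

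Per the file headers, the array images were read with Agilent Feature Extraction 9.5.3.1 on a whole mouse genome design whose probe coordinates are given on build mm8. The mean and background intensity of each spot in both colours were deposited without background subtraction, per the file headers. Feature Extraction also wrote processed intensity values, background-subtracted and dye-normalized, together with a log10 ratio of Cy5 over Cy3 and a p-value of that ratio from its error model of a single array, per the file headers. The deposited value table of the series held 40477 probes. Setting it against the scanner values showed log2 ratios of knockdown over control, equal to the deposited log10 ratio on a log2 scale within 0.001 for 99.4% of the probes with a value on each array, with a median of 0 on both arrays. It was blank for 1165 probes on array 1 and 2004 on array 2. Why those values were blank stayed unknown.

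Signals were corrected with normexp at an offset of 50 on the mean signal and local background median, and log2 ratios were normalized within each array by loess with a span of 0.3, in limma 3.58.1 under R 4.3.3. The 1639 control spots had weight 0 in the loess and were then left out, as were spots with a non-uniformity or population outlier flag, 154 on array 1 and 237 on array 2. Saturated spots were kept. Spots of 1 probe were averaged. Of 41174 distinct probes, 23374 were named through their accession in the RefSeq gene table of mouse assembly GRCm38.p6, 6733 carried a current symbol, 2919 were renamed through a synonym, and 8148 kept the name in the file. A probe was tested where it was well above background in at least 1 channel on both arrays, and each gene was represented by its brightest probe, which left 18065 genes. Of these, 6139 had more than 1 tested probe. Where a gene's RNA was not well above background in a channel on both arrays, its fold was taken against a floored level. That level was the channel's reading or, where higher, the lowest level of probes well above background, per channel after loess and Aquantile. Where the reading was the higher, this fold equals the mean ratio and is no bound. It also stays open to dye bias.

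Each gene's log2 ratio was tested against 0 with limma (lmFit with an intercept, eBayes, two-sided) and Benjamini-Hochberg adjustment, with calls at an adjusted p of 0.05. With 2 arrays the fit had 1 residual degree of freedom, and an exact sign-flip test cannot give a p below 0.5. Genes with a ratio of at least 2-fold in the same direction on both arrays were counted beside it, with no test. The 20 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists, with camera at an estimated correlation and fry beside it. At the preset correlation camera sets the genes of a list against all other genes. Its p-values there rest on the spread across genes and do not measure the spread between replicates. With an estimated correlation camera uses the 1 residual degree of freedom instead, as fry for 1 direction does. Only a very large statistic could then pass, so a list that missed the threshold there is not argued against. With 2 arrays the estimated correlation reflects only how many members shared the sign of the difference between the arrays. The lists covered myogenic transcription factors, contractile and excitation genes, adhesion and fusion, inhibitors of differentiation, chromatin repressors, ribosome biogenesis, p53 targets, cell cycle, cell cycle inhibitors, oxidative metabolism, NF-kappa-B targets, interferon response, extracellular matrix, insulin-like growth factor signalling, stress response, and markers of adipocytes, osteoblasts and chondrocytes, endothelium, leukocytes and neural cells. Each list's median was also ranked among 10000 random lists of the same size matched on intensity in 20 bins, separately on each array.

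The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named Mybbp1a, the 12 genes with the largest and the 12 with the smallest ratio past the threshold or, where too few passed, the largest ratios among genes at least 2-fold on both arrays, 10 fixed muscle genes, and Hdac1, Hdac2, Cdkn1a, Ppargc1a, Hprt, Gapdh and Actb. Per list it named the extreme members past the threshold, of which there were none. List members named beyond it were chosen after their values were seen, as examples of the list.

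The pipeline was tested on simulated arrays of the same 18065 genes, with noise drawn from the fitted prior and 50 changed genes of each size. Of those changed by 0.5, 1, 2 and 4 on the log2 scale, 0%, 4%, 82% and 94% were called, with 5 false calls among 17865 unchanged genes. With a spread of 0.2 times the real one, 88% of those changed by 0.5 were called. These shares depend on how many changes were planted and on their size, so they are not the power of the real comparison. There Ccdc80, at a mean of 4.20, was not called (limma adjusted p 0.178). Of the 20 lists, a list shifted by a planted 0.4 was called with an estimated median of 0.35, and 0 of the other 19 were. The simulated noise was independent between genes. Most genes of the real ribosome biogenesis list differed between the arrays in the same direction, which gave an estimated correlation of 0.78. The simulation therefore cannot show how often lists of correlated genes are called falsely. Alternatives covered the background correction, the processed signals, the deposited table, normalization, the probe filter, the choice of probe, the prior, the thresholds, the list tests and leaving out each array. A regression on probe base counts and the count from Feature Extraction's own p-values were added after the data were seen. Figures were drawn with matplotlib 3.10.9. With 2 arrays, their number limits the precision.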

Results

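C2C12 myoblasts, mouse muscle precursor cells that proliferate in serum-rich medium and fuse into myotubes when serum is withdrawn, were profiled after stable knockdown of Mybbp1a. The protein it encodes, Myb-binding protein 1a, is found mainly in the nucleolus and binds several transcription factors. The comparison asked which transcripts differ when Mybbp1a is depleted in undifferentiated myoblasts, and whether genes of the myogenic program are among them. The data were 2 two-colour arrays, each with knockdown RNA in Cy5 and control RNA in Cy3, of 45018 spots. The median spot signal was 329 in Cy5 and 159 in Cy3 on array 1, over background medians of 52 and 44.5. On array 2 it was 449 and 184, over 52 and 44. Spots well above background made up 65.6% in Cy5 and 64.9% in Cy3 on array 1, and 79.7% and 72.9% on array 2. Values below are log2 ratios of knockdown over control with their SD over the 2 arrays.

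Mybbp1a itself was lower in the knockdown cells on both arrays. Its log2 ratio was -1.64 on array 1 and -1.91 on array 2, a mean of -1.78 ± 0.19 (SD, n = 2) or 3.42-fold lower, with a limma standard error of 0.11. The transcript was measured by 1 probe, A_51_P332627, a 60-mer placed at positions 72266961 to 72267122 of chromosome 11 on mouse build mm8. These positions cover 162 bp, more than the length of the probe. The limma adjusted p was 0.178, which did not pass the threshold, and it was the lowest value in the fit, shared by 107 genes. Both dyes read this probe well above background on both arrays.

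No gene passed an adjusted p of 0.05 in limma, with 0 higher and 0 lower of 18065 tested. At an unadjusted p under 0.05, 2414 genes were higher and 1346 lower, against 903 in either direction that chance alone would give. The same 0 and 0 came from Feature Extraction's processed signals. Median centring in place of loess gave 3045 higher and 58 lower, while the median of all tested genes stood at 0.21. The log2 ratios of the 2 arrays correlated across genes with a Pearson r of 0.53 and a Spearman rho of 0.56, and 70.0% of genes had the same sign. Genes are not independent replicates, so these values describe the arrays only. The SD of the log2 ratios across genes was 0.31 on array 1 and 0.43 on array 2.

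Genes at least 2-fold apart on both arrays were mostly higher in the knockdown cells. Of them 114 were higher and 10 lower, so 91.9% were higher (exact binomial interval 85.7% to 96.1%, for counting error only). Independent arrays would have shared 6.93 and 0.20 genes. A further 9 genes were at least 2-fold apart in opposite directions. On array 1 alone 254 genes were at least 2-fold higher and 24 lower, and on array 2 alone 493 and 151. Of the 41 such genes with more than 1 tested probe, 39 had all their other probes on the same side. For 6 of the higher genes the control was not well above background on either array, so that the size of their ratio is uncertain.

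None of the 12 largest of these ratios passed the test. Ccdc80, a secreted protein of the extracellular matrix, had the highest ratio, 3.99 on array 1 and 4.40 on array 2 (mean 4.20 ± 0.29, 18.3-fold). Col1a1, a chain of type I collagen, had a mean of 3.16 ± 2.05, since it read 1.71 on array 1 and 4.60 on array 2. Adamts2, which trims procollagens, had a mean of 2.23 ± 0.26. Spon2, a secreted matrix protein, had 2.30 ± 1.13, and the growth factor Ptn had 2.21 ± 0.54. Tmem45a had a mean of 2.74 ± 0.26 and Gpm6b, a membrane glycoprotein best known from neurons, 2.49 ± 0.90. The remaining genes of the 12 were Lrmda at 2.43 ± 0.67, Afap1l1 at 2.37 ± 0.34, Ott at 2.36 ± 0.05, Ripk3, a kinase of necroptosis, at 2.31 ± 1.78, and Cys1 at 2.27 ± 0.40. The control channel of Afap1l1 was well above background on 1 of the 2 arrays. With the processed signals Afap1l1 had 3.69 and Adamts2 3.36. Whether the probe of Ott, an X-linked gene, also binds related sequences could not be checked. Adjusted p-values of these 12 genes in limma ran from 0.178 for Ccdc80 to 0.216 for Ripk3.

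**Figure D1:**
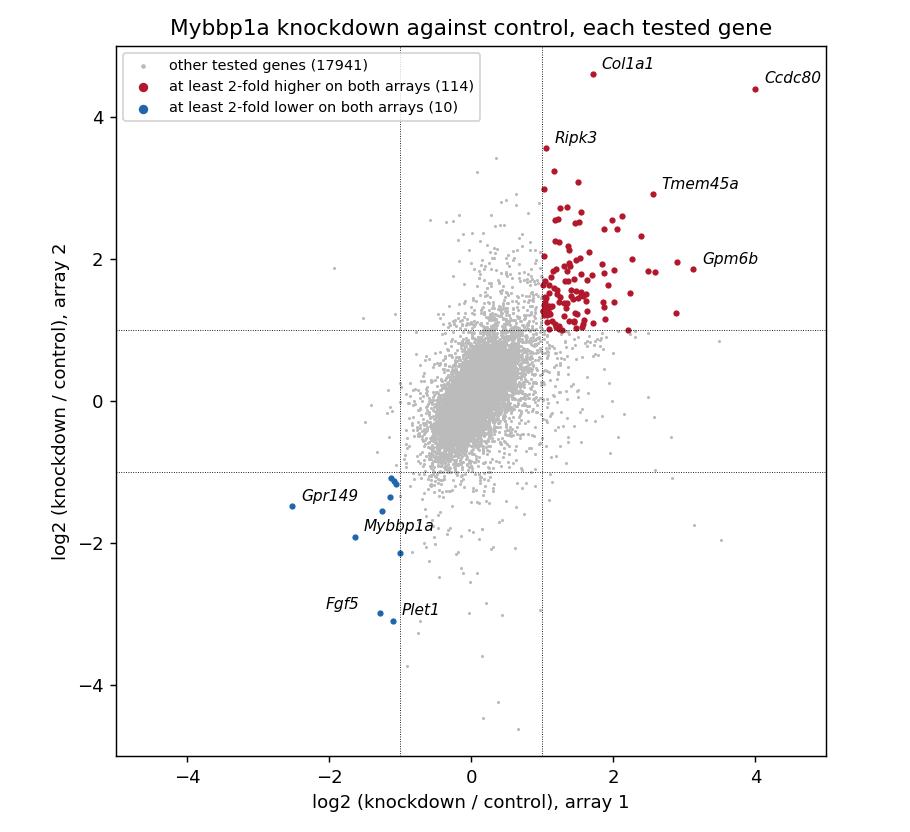
Each point is 1 of the tested genes, with its log2 ratio of knockdown over control on array 1 (x) and array 2 (y); dotted lines mark 2-fold. The 114 red genes and 10 blue genes are at least 2-fold apart in the same direction on both arrays, and Mybbp1a lies at -1.64 and -1.91.

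Besides Mybbp1a, 8 genes with a symbol were at least 2-fold lower on both arrays. Fgf5, a fibroblast growth factor, had a mean of -2.13 ± 1.19, with -1.29 on array 1 and -2.98 on array 2. Plet1 had -2.10 ± 1.41 and the receptor Gpr149 -2.00 ± 0.73. Ngfr, the low-affinity neurotrophin receptor, had -1.57 ± 0.81, and Stmn4, a stathmin that binds tubulin, -1.40 ± 0.20. Msmo1, an enzyme of cholesterol synthesis, had -1.11 ± 0.03 and the secreted hormone Stc2 also had -1.11 ± 0.03. Ano1, a calcium-activated chloride channel, had -1.25 ± 0.15, and since its knockdown channel was not well above background it was at least 2.17-fold lower. Ngfr had -0.89 as the mean over its probes, Msmo1 -0.65 under median centring, and with the processed signals Stc2 had -1.74 and Ano1 -2.91. Adjusted p-values in limma ran from 0.178 for Stc2 to 0.202 for Plet1, so none of these genes was called. They were the only 9 genes with a symbol, Mybbp1a included, that fitted the naming rule in this direction.

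The muscle regulators did not move as a group past the test. The 16 tested myogenic transcription factors had a median of 0.20, 0.05 on array 1 and 0.36 on array 2, with a camera adjusted p of 0.176. Adjusted over the list alone, 2 of them were higher and 1 lower, while over all genes tested 0 were called. Myog, which drives terminal differentiation, had 0.65 ± 0.20, with 0.79 on array 1 and 0.51 on array 2. Myf5, a determination factor of the lineage, had 0.40 ± 0.27. Myod1, the founding member of that family, had -0.20 on array 1 and 0.36 on array 2, a mean of 0.08 ± 0.40, and Mef2c had a mean of -0.25 ± 0.42. Limma adjusted p-values were 0.183 for Myog, 0.235 for Myf5, 0.814 for Myod1 and 0.486 for Mef2c. Median centring gave Myog 0.85 (adjusted p 0.0309), Myf5 0.65 (0.0418), Myod1 0.36, Mef2c -0.06 and the list 0.40, still uncalled, and the mean over probes put the list at 0.09. Tead4, named after its value was seen, had -0.67 on array 1 and -0.88 on array 2.

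Genes of the contractile apparatus and of muscle excitation showed no common direction. The 51 tested members had a median of 0.08, 0.12 on array 1 and 0.00016 on array 2, with a camera adjusted p of 0.554. On both arrays 23 were higher and 11 lower, and adjusted over the list alone 0 were called. Myh3, the embryonic myosin heavy chain, had 0.40 ± 0.33, with 0.63 on array 1 and 0.16 on array 2. Its control was not well above background on either array. Acta1, skeletal alpha-actin, read 1.19 on array 1 and -0.40 on array 2, and Myl1, a myosin light chain, -0.30 and -1.78. Ckm, muscle creatine kinase, had 0.02 ± 0.03 and Des, the muscle intermediate filament protein, 0.13 ± 0.11. Mymk, the membrane protein required for fusion, had -0.03 ± 0.02. The list of adhesion and fusion genes, 21 tested, had a median of 0.14 and a camera adjusted p of 0.143, with 3 higher and 1 lower adjusted over the list alone. Inhibitors of myogenic differentiation, 26 tested, had a median of 0.20 and an adjusted p of 0.101, with 1 higher and 0 lower adjusted over the list alone. These inhibitors passed the threshold with no filter on dim probes (0.17, adjusted p 0.0388), with both channels above background (0.20, 0.0489), after the base composition regression (0.19, 0.0480) and under median centring (0.47, 0.0482). Median centring put the adhesion list at 0.42, the contractile list at 0.16, Des at 0.46, Mymk at 0.18 and Ckm at -0.12. With the processed signals the contractile list had 0.02, Myh3 1.08 and Acta1 0.73. The lowest value of Myh3 over the alternatives was 0.19.

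**Figure D2:**
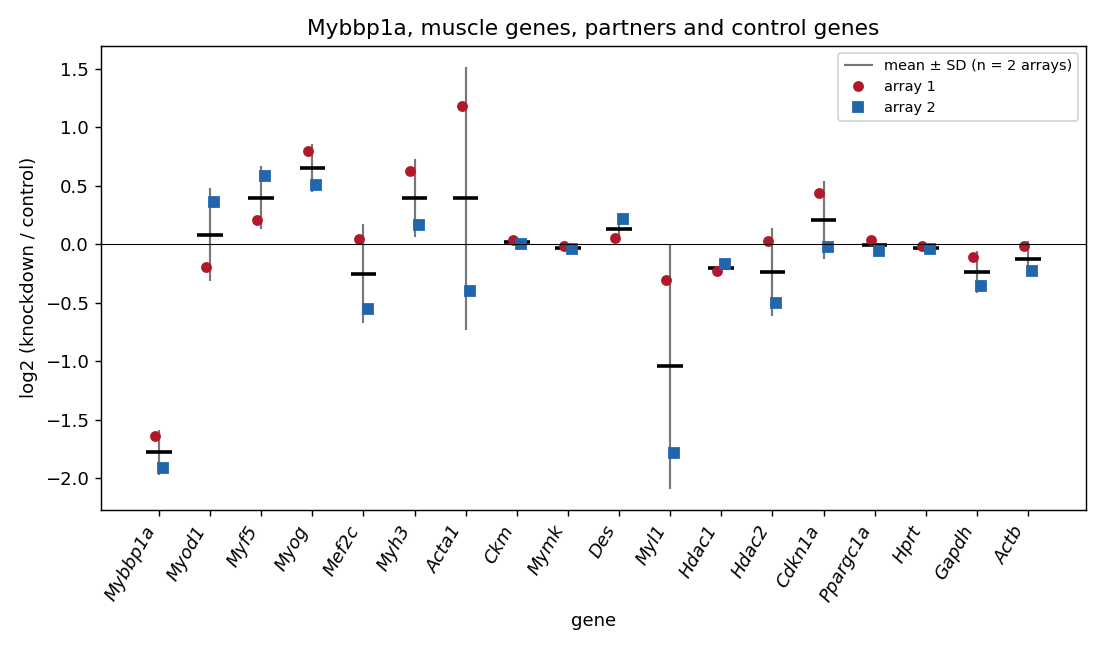
Log2 ratio of knockdown over control for Mybbp1a, the fixed muscle genes, and the fixed partner, target and control genes; circles are array 1, squares array 2, black bars the mean and grey lines the SD (n = 2 arrays). Mybbp1a sits at a mean of -1.78, while Myog lies at 0.65 and Acta1 falls on opposite sides of 0 on the 2 arrays.

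Genes for RNA polymerase I and ribosome assembly fell as a list. All 53 members were tested, with a median of -0.44, and 45 were lower on both arrays while 2 were higher on both. The camera adjusted p was 9.5e-15 with the preset correlation. With an estimated correlation, here 0.78, camera gave an adjusted p of 0.520, and fry gave an adjusted p of 0.347. The median was -0.23 on array 1 and -0.68 on array 2, at the 0th percentile of matched random lists on both. The cell cycle list was also at 0 on both, and the interferon and matrix lists were at 100 on both. On array 1 and array 2, myogenic transcription factors stood at 65.7 and 99.9, contractile genes at 99.2 and 10.9, and NF-kappa-B targets at 100 and 98.7. Median centring put the ribosome list at -0.11, with 0.12 on array 1 and -0.36 on array 2, against 0.21 for all tested genes. Examples, chosen after their values were seen, were the small-subunit assembly factor Pno1 (-0.56 and -1.19), the pseudouridine synthase Dkc1 (-0.53 and -1.19) and nucleolin, Ncl (-0.50 and -0.79). Npm1 went apart, at 0.24 and -0.52. None was called adjusted over the list alone, with 0 higher and 0 lower.

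Cell cycle and DNA replication genes also fell as a list. The 52 members had a median of -0.23, with -0.22 on array 1 and -0.21 on array 2, and 42 of them were lower on both arrays. The camera adjusted p was 8.1e-11 with the preset correlation of 0.01. With an estimated correlation, here 0.0045, camera gave an adjusted p of 0.520. That estimate lies below the preset, so it does not account for the loss of the call. The call was lost because this form of the test rests on 1 residual degree of freedom. Median centring turned the list's median to 0.15, below the 0.21 of all tested genes under that setting, and ended the call (adjusted p 0.241). Mcm10, a replication initiation factor, had -0.65 and -0.60, Ccne2 -0.38 and -0.71, and the proliferation marker Mki67 -0.36 and -0.08. Again 0 were called adjusted over the list alone. The 13 tested cell cycle inhibitors rose as a list, with a median of 0.29, 0.44 on array 1 and 0.40 on array 2, and a camera adjusted p of 0.0081. An estimated correlation, here 0.23, gave an adjusted p of 0.520 in camera. There were 5 higher and 0 lower adjusted over the list alone, and 7 were higher on both arrays. Their median was 0.57 under median centring. Cdkn1c had 0.76 and 1.18, Cdkn1b 0.46 and 0.70, and Cdkn1a, which is also in the p53 list, 0.44 and -0.03.

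Interferon response genes rose as a list. The 34 tested members had a median of 0.46, 0.34 on array 1 and 0.57 on array 2, and 28 were higher on both arrays. The camera adjusted p was 6.0e-08 with the preset correlation, and an adjusted p of 0.520 came with an estimated correlation, here 0.14. Adjusted over the list alone, 11 were higher and 1 lower. The membrane protein Bst2 had 1.19 and 1.86. Psmb8, a subunit of the immunoproteasome, had 1.65 and 2.09 against a control not well above background on either array. Genes of the extracellular matrix and markers of fibroblasts or smooth muscle, 42 tested, rose as a list with a median of 0.39 and a camera adjusted p of 4.3e-05. An estimated correlation, here -0.015 and so also below the preset, gave an adjusted p of 0.520 in camera too, again on 1 residual degree of freedom. The median was 0.65 under median centring. Adjusted over the list alone 12 were higher and 0 lower, and 29 were higher on both arrays. Col6a1 had 1.46 and 2.50, the receptor Pdgfrb 1.04 and 1.40, and the gelatinase Mmp2 0.49 and 2.83, whereas Ccn2 had 0.15 and -1.80 and Tnc -0.22 and -0.87.

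**Figure D3:**
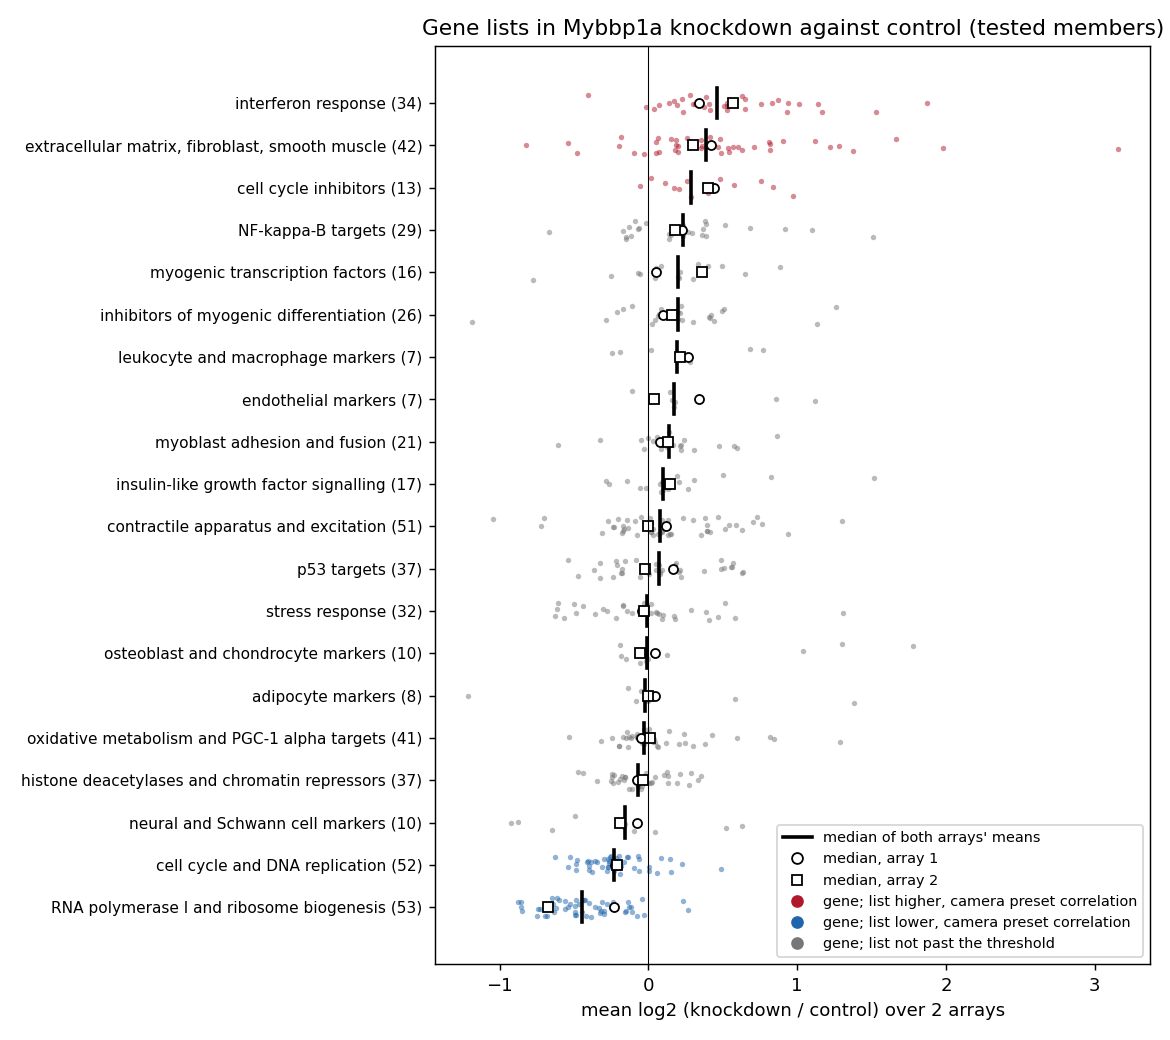
Mean log2 ratio of knockdown over control (x) for each tested member of the 20 gene lists, with the number tested in parentheses; thick bars are medians of the means, circles and squares the medians on array 1 and array 2. Lists past the camera threshold at the preset correlation are coloured, with ribosome biogenesis lowest at -0.44 and interferon response highest at 0.46.

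The other lists did not pass camera. Chromatin repressors had a median of -0.07 over 37 genes (adjusted p 0.101), and of the 2 histone deacetylases fixed in advance Hdac1 had -0.20 ± 0.04 and Hdac2 -0.23 ± 0.38, both above 0 under median centring. p53 targets had 0.07 over 37 genes (0.968), oxidative metabolism -0.03 over 41 (0.75) and NF-kappa-B targets 0.23 over 29 (0.120). Insulin-like growth factor signalling had 0.10 over 17 (0.176) and the stress response -0.01 over 32 (0.152). Among markers of other cell types, adipocyte genes had -0.02 over 8 (0.996), osteoblast and chondrocyte genes -0.01 over 10 (0.682) and endothelial genes 0.17 over 7 (0.101). Leukocyte and macrophage genes had 0.19 over 7 (0.176), and neural and Schwann cell genes -0.16 over 10 (0.120). The leukocyte list ran from 0.02 to 0.41 over the alternatives and stayed uncalled. For oxidative metabolism the mean was 0.07 and the test pointed down. For the osteoblast and adipocyte lists the mean (0.37 and 0.06) and the test pointed up. Median centring took oxidative metabolism (0.32, adjusted p 0.0138), NF-kappa-B targets (0.49, 0.0312) and neural markers (-0.05, 0.0494) past the threshold, and the deposited table also took NF-kappa-B targets past it (0.24, 0.0367). Median centring put insulin-like growth factor signalling at 0.45, p53 targets at 0.36, the stress response at 0.32 and chromatin repressors at 0.23, all uncalled, with all tested genes at 0.21. With an estimated correlation 0 of the 20 lists passed, and fry for 1 direction also passed 0. Both rest on 1 residual degree of freedom, so these counts do not argue against any list. Fry for changes in either direction passed 3: oxidative metabolism (adjusted p 0.0375), endothelial markers (0.0338) and neural markers (0.0338). Adjusted over the list alone, NF-kappa-B targets had 1 higher and 0 lower, insulin-like growth factor genes 1 and 0, oxidative genes 2 and 0, and adipocyte markers 2 and 1. Osteoblast, endothelial and leukocyte markers had 2 and 0 each, neural markers 1 and 2, and chromatin, p53 and stress genes 0 and 0. Such counts are not adjusted over the 20 lists. Among all 18065 tested genes, 2414 were higher and 1346 lower at an unadjusted limma p under 0.05, so a few per list are no particular result.

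Ppargc1a, a coactivator of oxidative metabolism, had -0.01 ± 0.07, and -0.30 to 0.10 over the alternatives. Of the control genes, Hprt had -0.03 ± 0.02, Actb -0.12 ± 0.15 and Gapdh -0.23 ± 0.18, and median centring put Hprt at 0.43 and Actb at 0.27. Gapdh ran from -0.41 to -0.10 over the alternatives. Its only tested probe was dim, with a mean log2 intensity of 8.30 against 15.6 for Hprt and 14.6 for Actb. The file placed the Actb probe on chromosome X, and which transcripts these probes read could not be checked. None of the 7 partner and control genes passed limma's threshold.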

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

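The spike-in controls, which no comparison above uses, gave far dimmer signals on array 1 than on array 2. Over 10 E1A controls of 32 spots each, the median signal above background in Cy5 was 319 on array 1 and 25776 on array 2, and in Cy3 it was 107 and 8573. Both lie above the negative control spots, whose medians in Cy5 were 5.18 and 12.7. They are listed here because they are a signal outside the reported measurement.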

How the results depend on the processing

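The results were recomputed under each alternative, and 2 of the settings, the base composition regression and the count from Feature Extraction's p-values, were chosen after the data were seen. The limma counts of 0 and 0 held under every alternative except median centring, which gave 3045 higher and 58 lower genes and moved the median of all tested genes to 0.21. Under it the Mybbp1a ratio was -1.50 with an adjusted p of 0.0275, against a range of 0.0275 to 0.179 over its alternatives, the cell cycle list turned to 0.15 and lost its call (adjusted p 0.241), ribosome biogenesis had -0.11 and kept its call, and 8 lists passed camera in place of 5, with inhibitors of myogenic differentiation (0.47, adjusted p 0.0482), oxidative metabolism, NF-kappa-B targets and neural markers gained. The deposited table gave 6 lists, with NF-kappa-B targets gained, and inhibitors of myogenic differentiation made it 6 with no filter on dim probes, with both channels above background and after the base composition regression. The cause of these differences was not tested, but median centring removes no intensity trend. Genes at least 2-fold on both arrays numbered 230 higher and 23 lower with the processed signals, 223 and 22 in the deposited table, 289 and 6 with median centring, 472 and 61 at 1.5-fold, and 455 and 83 by Feature Extraction's p-values. The last 2 settings use another criterion, and the cause of the others was not tested. With an estimated correlation 0 lists passed, and camera gave these 5 lists an adjusted p of 0.520 each. Their medians were -0.44 for ribosome biogenesis, -0.23 for the cell cycle, 0.29 for cell cycle inhibitors, 0.46 for interferon response and 0.39 for the matrix list. Fry also passed 0, with adjusted p-values of 0.347 for ribosome biogenesis and 0.263 for the other 4. Both tests rest on 1 residual degree of freedom and could hardly pass a list, so they do not argue against the 5. Leaving out 1 array gave 254 to 493 genes 2-fold higher and 24 to 151 lower, a ribosome biogenesis median of -0.68 to -0.23, a cell cycle median of -0.22 to -0.21, interferon response at 0.34 to 0.57, cell cycle inhibitors at 0.40 to 0.44 and the matrix list at 0.30 to 0.42, with no test, since no residual degrees of freedom remained. The myogenic transcription factor list stayed uncalled, at 0.09 to 0.40 with both arrays and 0.05 to 0.36 with 1, as did the contractile list, at 0.01 to 0.16 and 0.00016 to 0.12, and the correlation of the 2 arrays stayed within 1.5 times its value. Of results for single named genes and other lists, 28 kept their direction and passed a threshold they had missed, mostly under median centring. Oxidative metabolism also passed there, with the sign of its median turned. Of these single genes and other lists, 0 turned a call, while the called cell cycle list did turn its sign under median centring. Of the genes named, Myh3, Psmb8 and Ano1 were not well above background in 1 colour on both arrays, and Afap1l1 on 1 array.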

Other observations

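Groups of genes outside the fixed lists also shared a direction; the groups below were chosen after the values were seen, so their p-values measure the choice as much as the data. Enzymes of sterol synthesis and uptake were lower in the knockdown cells: 24 genes had a median of -0.53 on array 1 and -0.24 on array 2, and 17 were lower on both. Idi1 had -0.91 and -0.87, Cyp51 -0.73 and -0.74, and Hmgcs1 -0.87 and -0.63. Aminoacyl-tRNA synthetases and enzymes of serine synthesis had medians of -0.40 and -0.31, with 15 of 16 lower on both arrays, Phgdh at -0.58 and -0.77 and Aars at -0.75 and -0.46. Under median centring the signs no longer agreed: the sterol group had -0.18 on array 1 and 0.04 on array 2 and the synthetase group 0.03 and -0.02, with the median of all tested genes at 0.21. Camera at the preset correlation gave adjusted p-values of 4.2e-10 and 4.8e-09 over 7 such groups, and an estimated correlation gave 0.463 for each.

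Complement genes were higher: 9 tested genes had medians of 0.83 and 1.69, and 8 were higher on both arrays, among them C1s1 (1.69 and 1.77), C1ra (1.36 and 1.69) and Cfi (1.37 and 2.19). Genes of antigen processing and presentation, 3 of which are also in the interferon list, had medians of 0.35 and 0.58 over 14 genes, 11 higher and 2 lower on both arrays, with Tap2 at 1.06 and 0.75, H2-M3 at 1.55 and 0.62, B2m at 0.21 and -0.02 and Erap1 at -0.40 and -0.12. Glycolysis genes had medians of 0.26 and 0.45 over 18 genes, 14 higher and 3 lower on both arrays, with Pdk1 at 0.96 and 2.09, Gpi1 at 0.83 and 1.34 and Ldha at 0.66 and 1.01, whereas the lactate transporter Slc16a3 read 0.44 and -3.02. All 5 tested Magea genes, X-linked germline genes with near-identical copies that a probe cannot always separate, were higher on both arrays, with medians of 2.31 and 0.99. Of the genes at least 2-fold higher, 108 could be placed by symbol in the RefSeq gene table, and 8 of these were X-linked. Among all tested genes placed so, 454 of 14436 were X-linked (Fisher exact two-sided p = 0.0206, odds ratio 2.49, interval 1.04 to 5.14). The test took genes as independent and related genes were not merged, so Magea1, Magea8 and Ott each counted. Cytosolic ribosomal proteins had a median of 0.28 over 73 genes but 0.11 with the processed signals, 0.87 under median centring and -0.0047 in the deposited table, where 31 of them were tested. The glycolysis medians were 0.16 and 0.39 with the processed signals, 0.13 and 0.30 over the 13 genes tested in the deposited table, and 0.70 and 0.82 under median centring, which gave 0.76 and 0.86 for antigen processing. Complement genes had 1.02 on array 2 as the mean over probes and 1.08 with no filter on dim probes. For each of these 5 groups an estimated correlation gave an adjusted p of 0.463.

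Tests of the matters below were fixed before their results were seen, except the proliferation tests, the tests on whole chromosomes, the planted shifts and the amount taken from every ratio. The excess of higher over lower genes at 2-fold, 91.9% higher, was set against 3 technical explanations. A bias of the dyes with base composition is argued against, since the share was 90.4% after each array was regressed on probe base counts and intensity. That regression explained 1.71% of the variance on array 1 and 0.99% on array 2. A bias of the dyes that differs between probes in other ways stays open, since both arrays had the same dye orientation. Background correction of dim probes is argued against by the 90.0% among the brighter genes (exact interval 78.2% to 96.7%). The share also stood at 90.9% or more over 4 other normalizations. These 4 cannot exclude centring: the most that 1 of them lowered the median of all genes was 0.044, while 0.32 taken from every ratio would leave 60% higher, so centring stays open. Differences between the clone pools other than Mybbp1a stay open too: the labels name 1 source of knockdown cells, and no second hairpin or rescue was analysed here.

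The lower ribosome biogenesis list was at percentile 0 among random lists matched on intensity on both arrays, which argues against an intensity-dependent bias, and base composition left its median at -0.44. Slower growth of the knockdown cultures may lower such genes along with cell cycle genes. The ribosome list differed between the arrays by -0.39 and the cell cycle list by 0.034, a ratio of -0.086 (bootstrap interval -0.22 to 0.13). For the part that differs between the arrays this argues against proliferation, as far as cell cycle genes show it. A growth difference that leaves cell cycle genes unmoved was not tested. The bootstrap drew genes as independent, so its interval does not cover the spread between cultures. For the part the arrays share, slower growth stays open. The cell cycle list had a median of -0.23, lower but smaller in size than the -0.44 of the ribosome list.

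Genes of the same chromosome shared shifts, the largest of them on different chromosomes of the 2 arrays. On array 1 the median log2 ratio was 0.15 for 679 genes of chromosome 10, 0.17 for 460 of chromosome 16 and -0.05 for 755 of chromosome 8. On array 2 it was 0.22 for 496 genes of chromosome 14 and 0.18 for 597 of chromosome 15, and these 2 chromosomes had 0.01 and 0.02 on array 1. Chromosome 16 was also raised on array 2, at 0.07 (adjusted p 0.0089), while chromosome 10 had 0.03. Chromosome 8, at -0.0010 (adjusted p 0.0492), and chromosome 5, at -0.0075 and -0.0072, lay below the median of all genes on both arrays. The 5 largest shifts lay farther from the median of all genes than any of 10000 shuffles, and each showed it in both the first and the second part of the chromosome. A candidate explanation is a gain or loss of chromosomes in some clone pools. Over all 13 chromosome and array pairs past an adjusted p of 0.05, 46.2% showed the shift in both parts, too few for the test to decide. The search with windows of 31 neighbouring genes for copy number differences shared by both arrays found 0, but it found only 2% of chromosomes raised by a planted 0.2. Base composition is argued against, since the largest shift, of chromosome 14, was 0.19 after the regression.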
